A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

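Gene expression was measured in 5 temperature-sensitive strains of budding yeast, carrying the alleles cdc53-1, cdc34-3, cdc4-3, skp1-11 and skp1-25, with 1 array per strain at room temperature (25 °C) and 1 array per strain after 1 h at 35 °C. Per the labels' protocols, cells were grown in YPDA, a rich glucose medium with added adenine, total RNA was extracted, and biotin-labelled cRNA was made from it for Affymetrix arrays. The deposited values are on a log2 scale, which was inferred from their range because no label names the base. The probe summary, the background correction and the normalization are not given in the sources used here, nor is any filter that was applied before deposit. Array medians lay between 10.96 and 11.14, and no value was missing. The number of arrays limits the precision.

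The value table held 5716 probe sets. Of these, 5498 were paired with 1 gene symbol in the platform annotation, 0 with several, and 218 were unnamed and were not used. Symbols were updated through gene identifiers with a RefSeq gene table of assembly R64, which changed 12 symbols, and only its names were used. For the 47 genes with more than 1 probe set, the probe set with the highest mean over the 10 arrays was taken, which left 5449 genes. No filter on low values was applied in the main tests. Pearson correlations between arrays, across all 5716 probe sets, ran from 0.908 to 0.981, and no pair of arrays held identical values.

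Strain was taken from the labels and pairs the arrays, since both arrays of a pair carry the same allele and strain name. This was checked on the values: deviations from the mean of each temperature correlated, across genes, between the arrays of the same strain with r from 0.43 in cdc34-3 to 0.77 in skp1-11, whereas the highest correlation with an array of another strain was 0.12. The temperature shift was therefore fitted with strain as a block, and the 5 strains served as its replicates (residual degrees of freedom 4). Nothing in the labels says that cultures were repeated, so p-values measure the spread between strains. No strain with an intact SCF was analysed here, and the shift holds the response to warming together with the loss of SCF function.

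Linear models were fitted with limma 3.58.1 in R 4.3.3, using lmFit and eBayes, with Benjamini-Hochberg adjustment over all genes and a two-sided threshold of 0.05. Signatures of single gene products were sought on the 5 within-strain changes (35 °C minus room temperature). The skp1 alleles were set against the other 3 strains, and each strain in turn against the other 4, where the lone change is assumed to vary like the others. Changes within a strain alone have no replicate and were not tested.

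Before the data were examined, 27 gene lists were fixed, covering sulfur and other amino acid synthesis, cell cycle clusters, stress, ribosome, mating, nutrient and SCF genes. Of these, 24 were tested with camera at a preset inter-gene correlation of 0.01 and with an estimated correlation, and with fry, adjusted over the lists. The values of 1 tested list are not reported here, though counts of lists include it. Camera asks whether a list differs from the other genes. The directional p of fry asks whether the genes of a list move, on balance, one way, and does not compare the list with other genes. Counts adjusted over the list alone correct for the genes of that list, not for the number of lists or contrasts. Genes of a list can move together, so such counts are not counts of replicates. The a-specific, alpha-specific and auxotrophic marker lists only describe the strains. Within a strain, the median change of each list was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. A further list of 10 haploid-specific genes was written later, but before their values were seen as a set. Of these genes, FUS3, GPA1, FAR1 and RME1 were also in the earlier lists.

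Genes were named by a rule also fixed beforehand. For the temperature shift it takes the 10 largest rises and 10 largest falls among genes past the threshold that moved the same way in all 5 strains and whose mean at the temperature with the higher mean exceeded the median gene. For the contrasts between strains it takes the 5 largest differences each way among genes past the threshold, and none passed. For each strain alone it takes the 5 largest rises and 5 largest falls among genes whose higher value exceeded the median of that array. For each gene list it takes up to 4 members with the largest absolute moderated statistic. The SCF genes, SIC1, MET30, GRR1, the mating-type genes and the marker genes are always eligible.

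The fits were tested on simulated data made from the room temperature arrays and the spread of changes of each gene, with 200 of 5449 genes changed in each of 20 runs. The temperature fit recovered 57.9%, 90.1% and 98.0% of genes changed by 0.5, 1 and 2 (log2). The contrast of 2 strains against 3 recovered 0.025%, 42.5% and 86.9% of them, and that of 1 strain against 4 recovered 0%, 0% and 79.7%. Camera with the preset correlation called a simulated list of 30 genes shifted by 0.5 in 20 of 20 runs and an unshifted list in 0 of 20, with genes simulated as independent. These runs therefore do not show how often a list of correlated genes is called falsely. In the temperature shift the estimated correlations ran from 0.12 for SCF components to 0.96 for histone genes.

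Alternatives were quantile normalization, median centring, filters on low values, a floor at the 10th percentile, an intensity trend with robust variance, the mean of a gene's probe sets, array weights, no strain block, and leaving out each strain in turn. Restricting the temperature and cdc53-1 tests to genes above the median level, and leaving out the probe sets marked as matching several transcripts, were added after seeing the data.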

Results

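The SCF is a ubiquitin ligase that marks cell cycle and metabolic regulators for destruction. Cdc53 is its cullin scaffold, Cdc34 the ubiquitin-conjugating enzyme that works with it, Skp1 the adaptor, and Cdc4 an F-box protein that brings substrates such as the kinase inhibitor Sic1. Expression was compared in 5 strains with temperature-sensitive alleles of these genes, at room temperature (25 °C) and after 1 h at 35 °C, to find genes that respond to the loss of each product. There were 10 arrays, 1 per strain and temperature, and levels are on a log2 scale. Values given as mean ± SD are over the 5 strains.

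Transcripts of SCF genes were compared first. CDC53 averaged 11.71 ± 0.17 at room temperature and 11.44 ± 0.21 at 35 °C, and CDC34 averaged 10.60 ± 0.27 and 10.89 ± 0.35 (SD, n = 5 each), and neither difference passed the test. CDC4 rose by 0.36 ± 0.12 (adjusted p = 0.0164), and MET30, the F-box gene that represses sulfur amino acid synthesis, rose by 0.54 ± 0.28 (adjusted p = 0.0226), each in 5 of 5 strains. SIC1 differed by 0.14 ± 0.33 (adjusted p = 0.455) and GRR1 by -0.04 ± 0.18 (adjusted p = 0.795). SKP1 stood at 13.25 at room temperature and 13.33 at 35 °C in skp1-25, against 12.36 to 12.65 and 12.54 to 12.76 in the others. Temperature-sensitive alleles act on the protein, so these levels do not check the labels.

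The strains differed in mating-type and marker genes before any shift. In the cdc53-1 arrays the a-specific genes, which are expressed in haploid cells of mating type a, lay far below the other strains: STE2, the alpha-factor receptor gene, stood at 7.39 and 6.41 at room temperature and 35 °C, against 12.15 to 13.24 elsewhere, and the pheromone gene MFA2 at 6.90 and 6.36, against 12.26 to 13.26. BAR1, which encodes the protease that degrades alpha factor, was low in cdc53-1 (7.91 and 7.64), cdc4-3 (7.57 and 7.26) and skp1-25 (7.86 and 7.71), and stood between 11.65 and 12.11 in cdc34-3 and skp1-11. The alpha-specific genes had means at room temperature of 4.64 ± 0.52 for MF(ALPHA)1, 6.05 ± 0.25 for MF(ALPHA)2, 6.42 ± 0.38 for STE3 and 9.99 ± 0.38 for SAG1. Among auxotrophic markers, skp1-11 had HIS3 at 9.52 and 9.83 and ADE2 at 9.69 and 10.82, below the other 4 strains, and URA3 at 13.30 and 12.85, above them. Strain background therefore differs along with the allele in these comparisons.

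**Figure D1:**
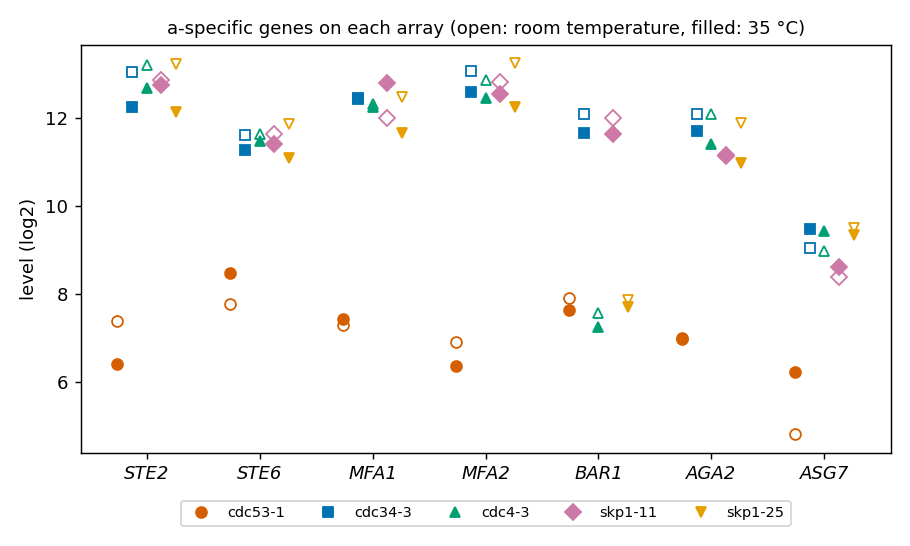
Levels (log2) of 7 a-specific genes on each of the 10 arrays, with strains by colour and shape, open symbols for room temperature and filled symbols for 35 °C. Both cdc53-1 arrays lie below the other strains for STE2, STE6, MFA1, MFA2, AGA2 and ASG7, and BAR1 is also low in cdc4-3 and skp1-25.

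At 35 °C, genes of stress and sulfur metabolism were among the largest rises, and genes of mitosis and amino acid synthesis among the largest falls. The small heat shock protein gene HSP26 rose from 11.10 ± 0.63 to 13.77 ± 0.23, a 6.35-fold increase (SD, n = 5; adjusted p = 0.00307). NQM1, a transaldolase paralog, rose by 2.52 ± 0.65, the aldehyde dehydrogenase gene ALD3 by 2.28 ± 0.43, the cell wall protein gene SPI1 by 2.24 ± 0.64, and the peroxiredoxin gene TSA2 by 1.88 ± 0.35. Sulfur genes among the largest rises were JLP1 (2.33 ± 1.47), the cystathionine beta-lyase gene STR3 (1.99 ± 1.00) and the siroheme synthesis gene MET8 (1.57 ± 0.61), and GPG1 (2.15 ± 0.37) and GPM2 (1.67 ± 0.69) completed the 10. JLP1 rose by only 0.06 in skp1-25, where the other strains ranged from 2.07 to 3.67. Adjusted p ran from 0.00137 for GPG1 to 0.0275 for JLP1. Falls were smaller. PGM1, a phosphoglucomutase gene, fell by 1.00 ± 0.54 (adjusted p = 0.0199), the peroxidase gene GPX2 by 0.92 ± 0.20, and the leucine and lysine synthesis genes LEU2, LEU1 and LYS9 by 0.88 ± 0.23, 0.84 ± 0.25 and 0.83 ± 0.23. SWI5, CHS2 and CDC5, which act in mitosis and cytokinesis, fell by 0.84 ± 0.36, 0.81 ± 0.29 and 0.79 ± 0.33, followed by the amino acid permease gene GAP1 (0.78 ± 0.48) and AIM20 (0.75 ± 0.32). Without an SCF-intact strain, effects of warming and of SCF loss are joined in these values.

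In all, limma called 706 genes higher and 251 lower at 35 °C out of 5449, and 690 and 248 of them moved the same way in all 5 strains. The test uses the same 5 changes and favours genes that agree in sign, so the sign counts add no separate evidence. At least a 1 log2 difference was reached by 142 of the higher and 15 of the lower genes. The balance depended on scaling: 73.8% of calls were higher with the values as deposited, 53.1% after median centring (539 higher, 477 lower) and 48.4% after quantile normalization (500 higher, 534 lower). Without the strain block, 282 were higher and 67 lower. With fewer strains in the fit, the counts fell to 514 higher and 124 lower without cdc53-1, 515 and 125 without cdc34-3, 291 and 80 without cdc4-3, 360 and 128 without skp1-11, and 527 and 136 without skp1-25. JLP1 missed the threshold when cdc53-1, cdc34-3, cdc4-3 or skp1-11 was left out (adjusted p = 0.0643, 0.0643, 0.0912 and 0.0834), GAP1 without cdc53-1, cdc34-3 or skp1-25 (0.0700, 0.0731 and 0.0724), PGM1 without cdc53-1 or skp1-11 (0.0502 and 0.0539), and SWI5 without cdc4-3 (0.0521).

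Sulfur amino acid genes, which are controlled by the SCF through Met30, had the highest median of the 24 tested lists. Of 29 measured, 22 rose and 0 fell (25 rose when adjusted over the list alone), and the list median was 0.75. MET32, a transcription factor gene of the pathway, rose by 1.56 ± 0.46, MET1 by 1.33 ± 0.39, the sulfate permease gene SUL2 by 1.42 ± 0.46 and MHT1 by 1.06 ± 0.36. Camera gave adjusted p = 4.02e-10 at the preset correlation, and adjusted p = 0.56 with an estimated correlation. The list median was above 0 in 5 of 5 strains, from 0.36 in cdc53-1 to 1.09 in skp1-11. It was 0.56 in cdc4-3, whose mutated F-box protein is not Met30. A part of Met30 in the rise was not tested.

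General stress genes driven by Msn2 and Msn4 rose in 18 of 30 (23 adjusted over the list alone), with GAC1 up by 1.66 ± 0.11, TFS1 by 1.52 ± 0.24 and HSP12 going from 13.05 ± 0.31 to 14.35 ± 0.22. Camera gave adjusted p = 8.04e-10, and adjusted p = 0.56 with an estimated correlation. Heat shock chaperone genes rose in 14 of 27 (14 adjusted over the list alone), with SSA4 up by 1.41 ± 0.40, SSA3 by 1.21 ± 0.37 and the polyubiquitin gene UBI4 by 0.52 ± 0.10 (camera adjusted p = 0.000614, and adjusted p = 0.76 with an estimated correlation). The chaperone list had a median of only 0.04 in cdc34-3. Cell wall integrity genes rose in 11 of 16 (14 adjusted over the list alone), among them GSC2, a glucan synthase gene also called FKS2, from 11.59 ± 0.64 to 13.09 ± 0.53, the MAP kinase gene SLT2 by 0.63 ± 0.15, PST1 by 1.06 ± 0.39 and YPS3 by 1.36 ± 0.58 (camera adjusted p = 2.73e-06, and adjusted p = 0.56 with an estimated correlation). Endoplasmic reticulum folding genes rose in 5 of 11 (8 adjusted over the list alone), with the oxidase gene ERO1 up by 0.58 ± 0.24 and the chaperone genes JEM1 and SCJ1 by 0.56 and 0.35 (camera adjusted p = 0.00492, adjusted p = 0.76 with an estimated correlation, and 0.0930 by fry).

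Early meiosis genes rose in 6 of 13 (9 adjusted over the list alone), from low levels: MEK1 went from 4.26 ± 0.60 to 5.68 ± 0.54, MEI4 from 7.10 ± 0.55 to 8.47 ± 0.43, ZIP1 rose by 0.92 ± 0.53 and the regulator gene IME1 by 0.56 ± 0.18. Camera gave adjusted p = 0.000297, and adjusted p = 0.56 with an estimated correlation. In 5 bins of genes by mean level, the dimmest bin also had a median difference of 0.16, against 0.02 in the brightest. Random lists matched more finely on level moved further in most strains. Their median change was 0.275 in cdc53-1, 0.302 in cdc34-3, 0.26 in cdc4-3, 0.302 in skp1-11 and 0.05 in skp1-25. The early meiosis medians there were 0.765, 0.302, 0.681, 0.699 and 0.512. Glycolysis genes had a median difference of 0.11, with 1 of 14 called, TDH1, which rose by 0.87 ± 0.28 (1 adjusted over the list alone). Their camera call (adjusted p = 0.0375, and adjusted p = 0.76 with an estimated correlation) was lost under both rescalings (adjusted p = 0.204 and 0.142) and without cdc53-1, cdc34-3, cdc4-3 or skp1-11 (adjusted p = 0.0853, 0.0560, 0.0654 and 0.0510).

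Mitotic genes of the CLB2 cluster fell in 10 of 18 and rose in 0 (11 fell when adjusted over the list alone). CDC20, an activator of the anaphase-promoting complex, fell by 1.07 ± 0.17, HOF1 by 1.11 ± 0.37 and the kinase gene KIN3 by 0.67 ± 0.25. Camera gave adjusted p = 8.04e-10, and adjusted p = 0.56 with an estimated correlation. Amino acid synthesis genes regulated by Gcn4 fell in 5 of 34 (3 adjusted over the list alone), where TRP4 fell by 0.46 ± 0.21 and BAT1 fell by 0.32 ± 0.11 (camera adjusted p = 0.000888, and adjusted p = 0.76 with an estimated correlation). The median of this list was 0.17 in cdc4-3 and below 0 in the other 4 strains, and fry gave adjusted p = 0.373. Ribosomal protein genes had a median difference of -0.02, with 1 of 128 higher, RPL9B, and 3 lower, RPS1A, RPL41A and RPL9A (0 adjusted over the list alone; camera adjusted p = 0.00179, and adjusted p = 0.76 with an estimated correlation). Ribosome biogenesis genes had a median of -0.03, with 1 of 44 lower, TIF6, which fell by 0.23 ± 0.07 (0 adjusted over the list alone; camera adjusted p = 0.0356, and adjusted p = 0.85 with an estimated correlation). After quantile normalization, where the median of all genes went from 0.05 to -0.03, the ribosomal protein median was -0.09 and that of ribosome biogenesis -0.11. The ribosome biogenesis call was lost without cdc4-3 (median -0.02, adjusted p = 0.112) and without skp1-11 (median 0.01, adjusted p = 0.422).

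Fry placed the sulfur, general stress, heat shock, cell wall, early meiosis and glycolysis lists higher and the CLB2 cluster lower (adjusted p from 0.0120 to 0.0443). The other 13 tested lists passed neither at the preset correlation nor with fry. Among those reported here, median differences were 0.03 for G1/S genes, -0.04 for histones, -0.02 for the MCM cluster, -0.09 for mating pheromone genes, 0.04 for glucose transport, -0.03 for the proteasome, 0.02 for respiration, 0.03 for phosphate genes, 0.06 for the iron regulon, -0.01 for ergosterol synthesis, 0.15 for DNA damage genes and 0.13 for SCF components. Camera placed G1/S genes lower although their median was above 0, with a mean of -0.01, and the iron regulon had a mean of -0.05. After quantile normalization the medians of the G1/S (-0.06), glucose (-0.03), respiration (-0.05), phosphate (-0.04) and iron (-0.02) lists were below 0. Those of histones (-0.13), the MCM cluster (-0.10), mating pheromone (-0.22) and ergosterol genes (-0.10) were lower than before it, as were those of DNA damage genes (0.04) and SCF components (0.05). G1/S genes were called higher without cdc53-1 (median 0.25, adjusted p = 0.0220) and lower without cdc34-3 (median -0.13, adjusted p = 0.00710). Proteasome genes were called lower after quantile normalization (median -0.11, adjusted p = 0.00515) and median centring (median -0.10, adjusted p = 0.00821), and without cdc4-3 (adjusted p = 0.0343) or skp1-11 (adjusted p = 0.00141), and respiration genes lower without cdc4-3 (median -0.04, adjusted p = 0.0493).

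**Figure D2:**
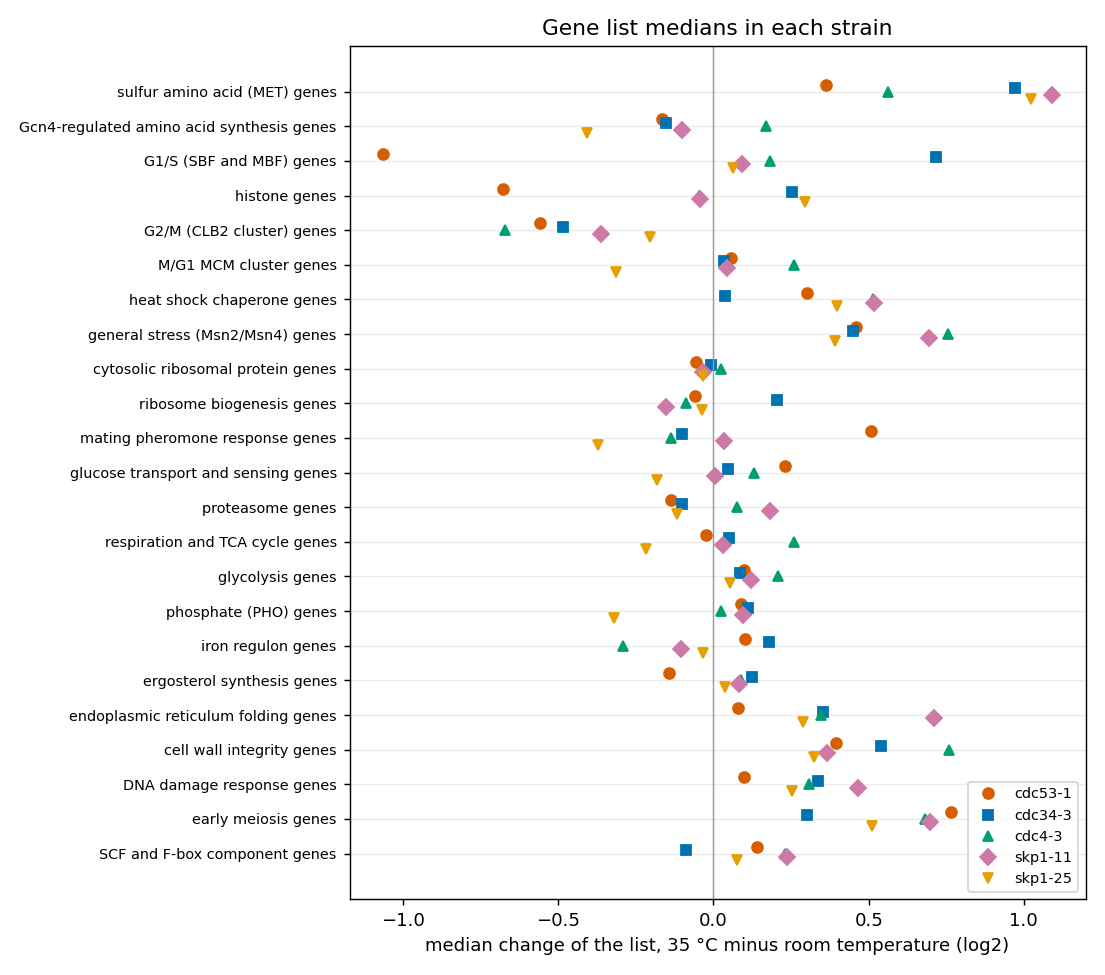
Median change (35 °C minus room temperature, log2) of each tested gene list reported here, 1 point per strain. Sulfur amino acid, general stress and cell wall lists lie above 0 in all 5 strains and the G2/M list below 0, while the G1/S list spans -1.07 in cdc53-1 to 0.72 in cdc34-3.

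G1/S genes of the SBF and MBF regulons separated cdc53-1 from the rest. Their median change was -1.07 in cdc53-1, against 0.72 in cdc34-3, 0.18 in cdc4-3, 0.09 in skp1-11 and 0.06 in skp1-25. The cyclin genes CLN1 and PCL1 had changes of -2.15 and -2.04 in cdc53-1, where the other strains ranged from -0.29 to 1.37 and from 0.06 to 1.41. Cohesin gene MCD1 (-1.71 against a mean of 0.44), TOS4 (-2.01 against -0.02), CDC21 (-1.06 against 0.26) and SWE1 (-1.22 against 0.49) showed the same direction. All 8 measured histone genes also had lower changes in cdc53-1, with a median of -0.68 against 0.14, and HTB2 at -1.98 against -0.03.

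No gene passed limma's test of cdc53-1 against the other 4 strains: 0 of 5449 were called (smallest adjusted p = 0.298), and 477 had an unadjusted p under 0.05. Adjusted over the list alone, 28 of 29 G1/S genes and 8 of 8 histone genes were lower. Camera placed both lists lower in cdc53-1 (adjusted p = 4.56e-27 and 4.22e-08), with adjusted p = 0.76 with an estimated correlation for each, and adjusted p = 0.17 by fry. In this contrast camera placed 4 lists higher and 5 lower at the preset correlation, and 0 lists were called with an estimated correlation (smallest adjusted p = 0.764) or by fry (0.172). Sulfur genes had lower changes in cdc53-1 (median 0.36 against 0.93; camera adjusted p = 1.84e-05, and adjusted p = 0.76 with an estimated correlation), with MET2 at -0.07 where the others ranged from 1.27 to 1.82, and MUP3 at -0.86 against 1.10. The median difference of sulfur genes from the mean of the other strains was 0.38 at room temperature and -0.06 at 35 °C, so the smaller change went with a higher starting level. Both cdc53-1 arrays also had low a-specific and haploid-specific genes, which go together with the allele in this contrast. Counts of list genes here rest on 1 pair of cdc53-1 arrays.

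**Figure D3:**
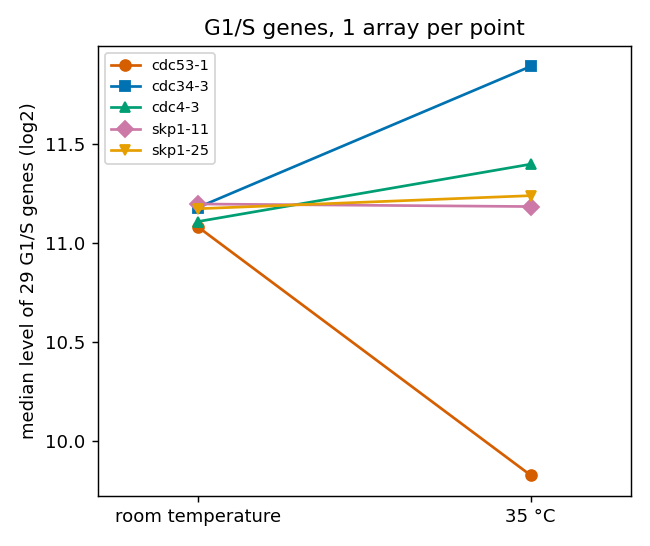
Median level (log2) of 29 G1/S genes on the room temperature and 35 °C array of each strain, joined by strain. The 5 strains lie between 11.08 and 11.20 at room temperature, and at 35 °C cdc53-1 lies at 9.83 and the others between 11.18 and 11.89.

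In cdc34-3, G1/S genes had higher changes and chaperone genes lower changes than the mean of the other strains. All 29 G1/S genes had a higher change than the mean of the other strains, with CLN1 at 1.37 and PCL2 at 1.09, though the mean of the others includes the low cdc53-1 values. Ribosome biogenesis genes had a median change of 0.21 against -0.09, with NOG1 at 0.65 and NSR1 at 0.52. Their median difference in level from the mean of the other strains was -0.22 at room temperature and 0.06 at 35 °C, so most of the higher change lay in the room temperature array. Heat shock chaperone genes had a median of 0.04 against 0.46, with the chaperone gene HSP78 at -0.04 against 0.82 and BTN2 at -1.34 against 0.12. Of the 27 chaperone genes, 24 had a lower change than the mean of the others and 3 a higher one. HSP26 still rose by 2.93 in cdc34-3, against a mean of 2.60 in the others, and SSA4 and SSA3 rose by 1.36 and 1.08. limma called 0 genes in this contrast (smallest adjusted p = 0.539; 392 at an unadjusted p under 0.05). Adjusted over the list alone, 1 chaperone gene was lower and 0 G1/S or ribosome biogenesis genes passed. At the preset correlation camera placed 5 lists higher and 2 lower, among them the G1/S (adjusted p = 1.95e-08), ribosome biogenesis (1.14e-09) and chaperone lists (2.32e-06). These 3 had adjusted p = 0.83 with an estimated correlation.

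In cdc4-3, the F-box mutant, respiration and Gcn4-regulated genes had higher changes and iron and sulfur genes lower changes than the mean of the 4 core component mutants, though sulfur genes changed less in cdc53-1. All 38 respiration genes had a higher change than the mean of the others (median 0.26 against -0.04), with FUM1 at 0.59 and ATP1 at 0.42. That mean includes the low values of skp1-25, with a median of -0.22, where cdc53-1, cdc34-3 and skp1-11 ranged from -0.02 to 0.05. Matched random lists in cdc4-3 had a median of 0.0955. Gcn4-regulated genes had a median of 0.17 against -0.18, with ARG3 at 0.16 against -0.82. Here too skp1-25 was lowest, at -0.41, where cdc53-1, cdc34-3 and skp1-11 ranged from -0.17 to -0.10. All 17 iron regulon genes had a lower change (median -0.29 against 0.14), with the siderophore transporter gene ARN2 at -1.43, and their median difference in level from the other strains was 0.17 at room temperature and -0.22 at 35 °C. Sulfur genes had a median of 0.56 against 0.84, where cdc53-1 alone had 0.36, with MET8 at 0.70 against 1.79. limma called 0 genes (smallest adjusted p = 1.00; 197 at an unadjusted p under 0.05), and 0 genes of these 4 lists passed when adjusted over the list alone. Camera placed 3 lists higher and 5 lower, among them respiration (adjusted p = 1.34e-08), iron (7.63e-07), Gcn4-regulated (5.48e-06) and sulfur genes (7.69e-05). These 4 had adjusted p = 0.97 with an estimated correlation. The lists placed higher numbered 5 without cdc53-1 and 6 without cdc34-3, and those placed lower 3 without cdc34-3.

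In the skp1 alleles, changes of sulfur genes were higher and those of cell wall genes lower than the mean of the other 3 strains, but not than every one of them by a clear margin. Sulfur genes had a median change of 1.10 in the skp1 pair against 0.59, where cdc34-3 alone had 0.97, cdc4-3 0.56 and cdc53-1 0.36, with STR3 at 2.87 against 1.40 and MET14 at 1.07 against 0.49. Cell wall genes had a median of 0.41 against 0.61, where cdc53-1 alone had 0.40, with YPS3 at 0.74 against 1.78, and mitotic genes -0.27 against -0.46, with HOF1 at -0.74 against -1.36. limma called 0 genes (smallest adjusted p = 0.588; 168 at an unadjusted p under 0.05), with 1 cell wall gene lower and 0 sulfur or mitotic genes called when adjusted over the list alone. Camera placed 6 lists higher and 8 lower, among them the sulfur (adjusted p = 2.53e-06), mitotic (3.24e-06) and cell wall lists (1.13e-05). These had adjusted p from 0.696 to 0.713 with an estimated correlation. The mitotic list missed the threshold without skp1-25 (difference 0.19, adjusted p = 0.229), and 3 lists instead of 8 were then lower.

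Changes in the single skp1-11 and skp1-25 pairs of arrays were also set side by side, and the alleles were not tested against each other. In skp1-11 the sulfate permease gene SUL1 went from 8.80 to 13.01, a change of 4.21 against -0.39 in skp1-25, and CHA1, the serine and threonine deaminase gene, had a change of -3.27 in skp1-11 and 2.77 in cdc53-1. Endoplasmic reticulum folding genes had a median of 0.71 in skp1-11 where the others ranged from 0.08 to 0.35, with SIL1 at 1.34, and proteasome genes 0.18 against a median of -0.08. In skp1-25 the phosphate genes SPL2 and PHO11 had changes of -1.64 and -1.31, and the phosphate list had a median of -0.32, where the others ranged from 0.02 to 0.11, while its median difference in level from the other strains was 0.23 at room temperature and -0.15 at 35 °C. limma called 0 genes for skp1-11 (smallest adjusted p = 0.542; 217 at an unadjusted p under 0.05) and 0 for skp1-25 (smallest adjusted p = 1.00; 227). Adjusted over the list alone, 4 phosphate genes were lower in skp1-25 and 0 folding or proteasome genes differed in skp1-11. Camera placed 6 lists higher and 3 lower in skp1-11, and 3 higher and 9 lower in skp1-25, with smallest adjusted p = 0.88 and 0.27 with an estimated correlation. Across genes, which are not independent replicates, the changes of the skp1 alleles correlated with r = 0.50, within the range of 0.41 to 0.59 over the 10 pairs of strains.

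Changes of at least 1 log2 within a strain, which have no replicate check, were seen for 329 genes in cdc53-1, 282 in cdc34-3, 311 in cdc4-3, 275 in skp1-11 and 208 in skp1-25. HSP26 was among the 5 largest rises in cdc53-1, cdc34-3, cdc4-3 and skp1-11, and NQM1 in cdc53-1, cdc34-3, cdc4-3 and skp1-25. Most of these genes were dim, and 109, 99, 107, 89 and 68 remained among genes above the 25th percentile of mean level. The sulfur, general stress and cell wall lists lay at or above percentile 99.99 of matched random lists in every strain, and the G2/M list at or below percentile 0.08. Random lists hold genes drawn independently, whereas genes of these lists can move together. The percentiles are therefore descriptive, with 1 pair of arrays per strain.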

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

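The tests of an exchange of the cdc53-1 arrays, of alpha mating type and of a different strain on 1 cdc53-1 array were chosen after the results they bear on were seen. Of 92 sets of 5 values examined, 19 had a strain far from the others, where chance gives about 1 in 20. Of these, 12 were the low levels of 6 a-specific genes in cdc53-1 at both temperatures: STE2 at 7.39 and 6.41, STE6 at 7.79 and 8.47, MFA1 at 7.29 and 7.44, MFA2 at 6.90 and 6.36, AGA2 at 6.99 and 6.97, and ASG7 at 4.81 and 6.22, at room temperature and 35 °C. The others stood at 8.38 or above for ASG7 and at 10.98 or above for the rest.

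For the low a-specific genes, a cdc53-1 strain of alpha mating type would have raised alpha-specific genes, but these stood only 0.38 above the mean of the other strains. A different strain on 1 of the arrays would have set the cdc53-1 pair apart, but their median absolute difference over the a-specific genes was 0.54, against a distance of -4.58 from the other strains. An a/alpha diploid represses haploid-specific genes. The 10 such genes had a median difference of -3.53 from the other strains, averaged over both temperatures. They were listed before their values were seen as a set, though FUS3, GPA1, FAR1 and RME1 were also in the earlier lists. Each of the 10 was below all other strains on both arrays, with HO at 4.62 against a mean of 11.17 and FUS3 at 5.88 against 11.13 at room temperature. These values are consistent with the hypothesis of an a/alpha diploid, but a haploid expressing both mating-type alleles, which was not tested, may give them too, and either would vary together with the allele wherever cdc53-1 is compared.

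The median G1/S level at 35 °C was lowest in cdc53-1, but the list's change was not among the 19, with a gap of 0.632 of the range. If the cdc53-1 arrays had been exchanged, its changes would run against those of the other strains, but they correlated with r = 0.605 across genes. An unusual room temperature array was argued against by the 35 °C level itself, a median of 9.83 against 11.18 or more in the other strains, with 29 of 29 genes below all of them. A shift of the whole array was argued against by a median change of -1.07 that lay below all 10000 matched random lists. A difference in how cdc53-1 cells stop in the cell cycle may underlie it, as may the strain's mating type, and with 1 cdc53-1 strain these stay open.

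Other results far from the rest were the change of TSA2 in cdc4-3 (2.49, others 1.59 to 1.83), the phosphate list in skp1-25 (-0.32, others 0.02 to 0.11), CDC4 at 35 °C in cdc53-1 (11.36, others 11.71 to 11.77) and SKP1 at 35 °C in skp1-25 (13.33, others 12.54 to 12.76). HIS3 stood at 9.52 and 9.83 and ADE2 at 10.82 (35 °C) in skp1-11, where the others were at 12.20 or above.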

How the results depend on the processing

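Restricting tests to genes above the median level and dropping probe sets that match several transcripts were chosen after seeing the data. No control or other-species probe sets were in the table used here, so the planned filter on background was not run and signal over background is unknown. All 20 named temperature genes kept their direction under each alternative that tested them: 267 of 288 values stayed on the same side of the threshold and 21 lost their call. The naming rule admits only genes that moved the same way in every strain. Leaving out a strain, dropping the strain block or weighting the arrays therefore could not turn their direction. For those alternatives the kept direction adds no separate evidence, and only the calls could change. Of 528 list values, 437 were the same, 64 lost a call, 23 gained one and 4 turned. All 6 contrasts between strains gave 0 genes in limma under every alternative run, with 137 to 510 genes at an unadjusted p under 0.05.

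Genes lower at 35 °C numbered 534 after quantile normalization and 477 after median centring, against 251, and higher genes 409 above the median level, where fewer genes were tested. Without the strain block, which pairs the arrays, 282 were higher and 67 lower, and 11 of the 20 named genes lost their call. With 1 strain left out, and so fewer samples, 291 to 527 were higher and 80 to 136 lower. Genes changed by 1 or more within cdc53-1, cdc34-3, cdc4-3, skp1-11 and skp1-25 numbered 109, 99, 107, 89 and 68 above the 25th percentile, where fewer genes were counted, and 175, 130, 157, 129 and 83 with a floor, which removes differences among dim genes. With an estimated correlation 0 lists were higher and 0 lower in the temperature shift and in all 6 contrasts, and fry called 1 list lower in the shift. With a strain left out, 4 to 6 lists were higher and 3 to 9 lower in the skp1 contrast, and 3 to 6 higher and 3 to 5 lower in the cdc4-3 contrast. With a strain left out, the G1/S median ran from -0.13 to 0.25 in the shift and from -0.35 to 0.46 in the skp1 contrast. Without cdc53-1, whose own G1/S genes were low, camera's direction turned in both (0.25 and -0.35), and the median in the shift, 0.03 with all strains, was lowest (-0.13) without cdc34-3. In the skp1 contrast, ribosome biogenesis genes ran from -0.20 to -0.0365, the last without skp1-11, where camera's direction turned, and phosphate genes from -0.42 to 0.18, the last without skp1-25, and the cause was not tested.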

Other observations

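No test in this part was chosen after its result was seen, but the medians by level bin were computed after the early meiosis rise was seen. Iron genes set skp1-25 apart at both temperatures. The median iron regulon gene stood 1.22 above the mean of the other strains at room temperature and 1.27 above it at 35 °C, with FIT2 at 13.47 at room temperature against 10.06 to 12.04 and ARN2 at 12.57 against 9.49 to 11.50. Within skp1-25 the list changed by a median of -0.03 with temperature. Respiration genes in the same strain had median differences from the other strains of -0.35 at room temperature and -0.62 at 35 °C. FIT2 and ARN2 were picked after their values were seen, and with 1 array per strain and temperature these differences have no test. In cdc53-1, mating pheromone genes, which include the haploid-specific FUS3 and GPA1, had a median difference from the others of -0.70 at room temperature and -0.42 at 35 °C.

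Early meiosis genes rose from low levels. Unequal array distributions as the whole cause would have left no rise after quantile normalization, but the list's median change, which averaged 0.59 with an SD of 0.19 over the 5 strains before it, averaged 0.30 with an SD of 0.14 after it, so they may account for part of the rise. A shift of all dim probe sets cannot be told apart from a response of these genes: the list lay above the bound set beforehand for matched random lists in 1 of 5 strains, where at least 3 were required, with percentiles from 96.9 to 98.1 in 4 strains and near the middle in cdc34-3. In 5 bins by mean level, the dimmest genes also had a median difference of 0.16. The matched random lists had medians of 0.26 to 0.302 in cdc53-1, cdc34-3, cdc4-3 and skp1-11, and 0.05 in skp1-25. In cdc34-3 their median equalled that of the early meiosis list, 0.302. A dim-probe shift may account for part of it too.

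Other groupings of the 10 arrays tested whether chance could give the temperature calls. Among 100 of the 126 ways to split the arrays into groups of 5, the real split, with 957 genes, was the 1 that gave as many. The highest other split gave 1 gene. Most of these splits keep both arrays of some strains in 1 group. With strain in the fit, the temperature change of those strains then enters the spread, which can lower the calls. The other splits drawn include 13 that also part all 5 strain pairs, and the highest of these gave 0. These 13 are among the within-strain exchanges described next and add no separate evidence. Exchanging arrays within strains, which respects the pairs, allows only 16 assignments, which is too few for a share under 0.05. The real assignment, with 957 genes, was the 1 with as many, and the highest other gave 0. Exchanging the arrays of only some strains also puts a temperature change shared by the strains into the spread. The count of 0 was therefore likely in advance and does not exclude chance.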
